A study of Homo sapiens with 6 samples.

How the data were processed

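Accessible chromatin was measured by ATAC-seq, in which a transposase cuts open DNA and leaves sequencing adapters at the cut, in U2OS cells, an established human osteosarcoma line. There were 3 libraries from wild-type (WT) cells and 3 from cells with a knockout of CRAMP1 (CRAMP1-KO). Per the labels' protocols, each library started from 50000 cells whose nuclei were released with detergents, was tagmented for 30 minutes and was amplified for 7 PCR cycles. The labels do not say whether the replicates were separate cultures or whether the CRAMP1-KO cells were 1 clone, so the p-values measure only the spread between these libraries, which may be technical.

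Per the submitters' processing notes, the authors used bcl2fastq 2.20.0, cutadapt 3.4, BWA 0.7.17-r1188, the hg19 genome build and MACS3. The MACS3 version and settings, the treatment of duplicate and mitochondrial reads, and any shift of reads for the transposase are not given in the sources used here. The authors deposited 6 peak lists, 1 per library, called without pooling. The deposited score of a peak was 10 times its −log10 q, truncated to a whole number. The deposited fold enrichment is the ratio of the pileup at the summit to the local background of the same library. The deposited −log10 p and −log10 q values rate each peak against that background, and q was at most 0.05 in every peak. The deposited lists hold no read counts. Score, fold enrichment and q are the authors' own values for a peak and were used to describe, rank or filter peaks within a list. Fold enrichment also served, with −log10 p, to solve a pileup and a background per summit, which were compared between libraries. Coordinates are those of hg19, counted from 1. Chromosomes 1 to 22 and X were used.

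Because fold enrichment and the Poisson −log10 p together fix the pileup and the background, both were solved for each summit. At least 99.99% of the peaks of every library gave a whole pileup within 1e-05. The lowest background of a library is the genome-wide rate, which scales with depth and fragment length. Divided by the lowest peak width, taken as a stand-in for fragment length, it gave a relative depth index. The total number of reads is unknown, so no counting interval is given. The solver was tested on simulated peaks and returned the true pileup in 100% of them.

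Overlapping peaks of the 6 libraries were merged into regions at a minimum overlap of 1 bp. A genotype-specific region had a peak in 3 of 3 libraries of one genotype and in 0 of 3 of the other. Peak sets were compared by the Jaccard index of covered bases. Values per library were compared by a two-sided exact permutation test over the 20 label assignments, which cannot give a p below 0.1 with 3 libraries against 3. Shares of peaks per chromosome, and per 1-Mb bin with a mean of at least 5 peaks, were tested with limma 3.58.1 in R 4.3.3, on log2 shares with a pseudocount of 0.5 for bins, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With simulated changes in 200 of the 2828 bins, limma called 49% of changes of 0.5 and 83% of changes of 1 on the log2 scale, and 0.23% of unchanged bins. The simulation gave all libraries the same mean shares, a fixed dispersion and as many rises as falls. Its rates therefore need not hold for the real bins. Genotype-specific regions were compared between chromosome classes with Fisher's exact test. The other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots used matplotlib 3.10.9.

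The chromosome classes, 25 windows at gene clusters and key genes, tests and most alternatives were fixed before the data were examined. Regions were named as the 5 per direction with the highest median −log10 q over the libraries that have them. Bins were named as the 5 per direction with the largest change, with runs of adjacent called bins counted as 1. CRAMP1 and H1 genes were named whatever their values, as were windows whose libraries did not overlap between genotypes. The values of 1 window are not reported here. Window limits were written by hand for hg19. The 10 gene windows were checked against a gene table of GRCh38.p14 for their chromosome and for the spacing of neighbouring H1 genes, which differed by at most 0.617 kb. No annotation of hg19 was used here, so peaks by annotation class, the class of genotype-specific regions and gene lists at promoters were not analysed here. Alternatives were stricter q limits, lists of equal length, other overlap rules, other bin sizes and scalings, covered bases, a replicate block and the removal of each library in turn. Leaving out chromosome 18, or 4 segments that shifted as a block, was chosen after seeing the data.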

Results

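Chromatin accessibility was compared between WT and CRAMP1-KO U2OS cells, with 3 ATAC-seq libraries each. CRAMP1 is known as a regulator of linker histone H1 genes, and H1 is a chromatin protein that binds between nucleosomes and is most abundant in compact, gene-poor chromatin. The design asks where accessible sites are gained or lost without CRAMP1. The deposited lists held 198875, 151646 and 132686 peaks in WT replicates 1, 2 and 3, and 133756, 139242 and 157997 in CRAMP1-KO replicates 1, 2 and 3.

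The targeted gene came first. In all 6 libraries a peak lay near the start of the CRAMP1 window on chromosome 16, reaching from 1661788 to 1662955 in WT replicate 1 and from 1661775 to 1662920 in CRAMP1-KO replicate 1. The window held 13, 9 and 9 peaks in WT and 9, 7 and 8 in CRAMP1-KO. Its share of all peaks was 0.642 ± 0.0436 per 10000 in WT and 0.561 ± 0.0972 in CRAMP1-KO (SD, n = 3; exact permutation p = 0.3), a difference within the spread. Its covered share did separate the genotypes, at 76.9 ± 2.34 bases per 1000000 in WT and 65.7 ± 7.35 in CRAMP1-KO (SD, n = 3; exact permutation p = 0.1, the smallest possible). Accessibility measures neither the edit nor the expression of CRAMP1, so these values do not check the labels.

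Among the H1 genes, H1-4 on chromosome 6 and H1-10 on chromosome 3 differed in peak shape, and H1-1 in the width of its second peak. At H1-4 each WT library had 2 peaks, as at 26156467 to 26157020 and 26157353 to 26158804 in WT replicate 1. Each CRAMP1-KO library had 1 joined peak, at 26156488 to 26159004 in replicates 1 and 3 and to 26159050 in replicate 2. Of all the regions shared by all 6 libraries, 5.53%, 3.35% and 5.03% held more than 1 peak in WT and 2.15%, 2.96% and 2.11% in CRAMP1-KO. The covered share of the H1-4 window, 25.3 ± 4.49 bases per 1000000 in WT and 30.5 ± 2.8 in CRAMP1-KO (SD, n = 3), did not separate the genotypes (exact permutation p = 0.2). The single peak at H1-10 spanned 4080, 4088 and 3897 bp in WT and 2420, 3117 and 3124 bp in CRAMP1-KO, where it started later, as at 129033386 in replicate 1 against 129031713 in WT replicate 1. The covered share of the H1-10 window overlapped between genotypes, at 46.8 ± 7.58 and 34.9 ± 4.71 bases per 1000000 (SD, n = 3; exact permutation p = 0.2). H1-1 had 2 peaks in every library. Its second peak spanned 544, 488 and 489 bp in WT and 579, 634 and 590 bp in CRAMP1-KO. How many shared peaks separate the genotypes by width in this way was not counted. H1-2 had 1 peak in every library except WT replicate 1 with 2, and no peak was listed in the windows of H1-3 and H1-5. The genes of topoisomerase II, which passes one DNA duplex through another, held 2 or 3 peaks per library at both TOP2A and TOP2B. The covered share of TOP2A was 19.8 ± 1.18 bases per 1000000 in WT and 17.7 ± 1.65 in CRAMP1-KO, without overlap (SD, n = 3; exact permutation p = 0.1, the smallest possible), and that of TOP2B overlapped.

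The number of peaks did not separate the genotypes. It was 161069 ± 34086 in WT and 143665 ± 12711 in CRAMP1-KO (SD, n = 3; exact permutation p = 0.7), and without WT replicate 1 the difference of CRAMP1-KO minus WT turned from -17404 to 1499. Peaks covered 81.8 ± 14.1 Mb in WT and 82.8 ± 8.02 Mb in CRAMP1-KO (SD, n = 3; exact permutation p = 1). Across the 6 libraries the number of peaks rose with the relative depth index (Pearson r = 0.993, exact permutation p = 0.00417, adjusted p = 0.00833; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted p = 0.0167). This was the 1 relation computed, and r was 0.952 without WT replicates 1 and 3, the libraries farthest from the median depth index. Median fold enrichment within a list was 4.25, 5.96 and 6.21 in WT and 6.20, 6.21 and 6.26 in CRAMP1-KO. Peaks had a median width of 385 ± 37.4 bp in WT and 450 ± 17.6 bp in CRAMP1-KO (SD, n = 3), with no overlap between genotypes (exact permutation p = 0.1, the smallest possible). In lists of equal length the widths were 440 ± 53.4 and 477.5 ± 34.0 bp and overlapped (SD, n = 3; exact permutation p = 0.6).

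**Figure D1:**
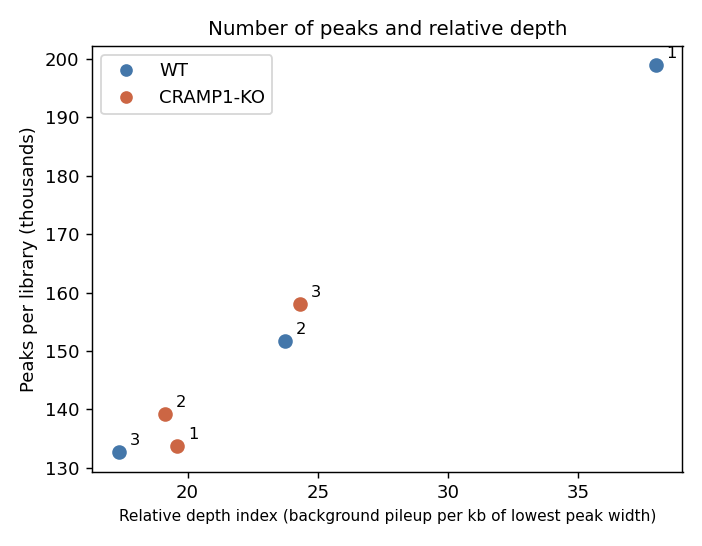
Number of peaks per library (y axis) against the relative depth index solved from the peak callers' values (x axis), with 1 point per library, coloured by genotype and labelled with the replicate number. WT replicate 1 has the highest index, 38.0, and the most peaks, 198875.

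A set of regions was called in all libraries of one genotype and in no library of the other. Of 248031 merged regions, 92505 (37.3%) had a peak in all 6 libraries, 1902 had one in all 3 CRAMP1-KO libraries and no WT library, and 2823 the reverse. In lists limited to the 132686 strongest peaks each, the counts were 2571 and 1859, so which direction held more regions turned with list length. The strongest CRAMP1-KO-only regions lay on chromosome 6 at 71062819 to 71063486, X at 118433989 to 118435571, 18 at 70319983 to 70320641, 3 at 151097074 to 151097410 and 18 at 64163211 to 64163548, with median −log10 q of 62.1, 60.3, 59.2, 55.8 and 51.9. The strongest WT-only regions lay on chromosome 3 at 155100290 to 155100460, 1 at 86094508 to 86095367, 12 at 4627680 to 4627846, 17 at 64251263 to 64251425 and 15 at 20703125 to 20703314, with median −log10 q of 85.8, 77.5, 63.3, 62.0 and 58.2. The CRAMP1-KO-only ones were 668, 1583, 659, 337 and 338 bp wide, and the WT-only ones 171, 860, 167, 163 and 190 bp. Lowest peak widths in the WT lists were 135, 163 and 147 bp, so most of the named WT-only regions were near the narrowest peaks. The treatment of duplicate reads is not given, and whether it bears on such narrow regions was not tested. These regions were not assigned to genes here. The rule loosens when a library is left out: there were 4523 CRAMP1-KO-only regions without WT replicate 1, 3975 without CRAMP1-KO replicate 1 and 3818 without CRAMP1-KO replicate 2, and 5838 WT-only regions without WT replicate 2, 8696 without WT replicate 3 and 5896 without CRAMP1-KO replicate 3.

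CRAMP1-KO-only regions lay more often on gene-poor chromosomes. Chromosomes 4, 13, 18 and X held 20.8% of CRAMP1-KO-only regions and 8.54% of WT-only regions, and the gene-rich chromosomes 16, 17, 19 and 22 held 8.46% and 16.5%. The odds of a gene-poor over a gene-rich chromosome were 4.75 times higher in CRAMP1-KO-only than in WT-only regions (Fisher's exact test, two-sided, adjusted p = 1.62e-39). Against regions with a peak in exactly 3 libraries of both genotypes, the odds ratio was 3.52 for CRAMP1-KO-only regions (adjusted p = 1.13e-39) and 0.742 for WT-only regions (adjusted p = 0.000491). Regions are not independent replicates, so these p-values describe the regions and not the spread between libraries.

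**Figure D2:**
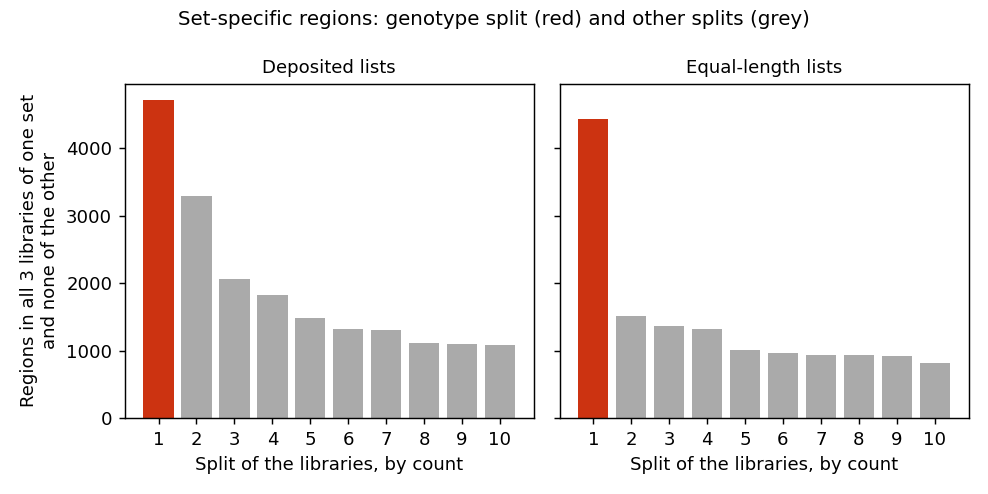
Number of regions with a peak in all 3 libraries of one set and none of the other, both directions summed (y axis), for each of the 10 splits of the 6 libraries into 3 and 3, ordered by count (x axis), for deposited lists (left) and lists of equal length (right). The genotype split (red) gives 4725 and 4430 regions, and the highest other split gives 3292 and 1509.

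On average, peak sets were more alike within than between genotypes. The mean Jaccard index of covered bases was 0.658 within and 0.627 between genotypes, with ranges of 0.599 to 0.685 and 0.595 to 0.663 that overlap. Only pairs of CRAMP1-KO libraries, at 0.677 to 0.685, lay above the range between genotypes. Pairs of WT libraries, at 0.599 to 0.654, lay inside it. The difference of 0.0313 was the highest of the 10 splits of the libraries, the smallest share that this design allows being 0.1. Without CRAMP1-KO replicate 1 the difference was 0.0159.

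As a class, the gene-poor chromosomes held a larger share of the peaks in CRAMP1-KO, but chromosome 13 within it did not. The ratio of peaks on chromosomes 4, 13, 18 and X to those on 16, 17, 19 and 22 was 0.681, 0.653 and 0.648 in the WT libraries and 0.731, 0.753 and 0.746 in the CRAMP1-KO libraries, with means of 0.661 ± 0.0179 and 0.743 ± 0.0114 (SD, n = 3). Every CRAMP1-KO library lay above every WT library (exact permutation p = 0.1, the smallest possible). Without chromosome 18, an alternative chosen after seeing the data, the ratio was 0.498 ± 0.00925 and 0.555 ± 0.0128, also without overlap (SD, n = 3; exact permutation p = 0.1).

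By chromosome, limma called 4 higher and 4 lower in CRAMP1-KO. Chromosome 18 rose by 0.16 on the log2 scale (SE 0.02, adjusted p = 0.00464), from 2.5% ± 0.0659 to 2.79% ± 0.0406 of the peaks (SD, n = 3; limma). Chromosome 4 rose by 0.14 (SE 0.02, limma adjusted p = 0.00551), 6 by 0.08 (SE 0.01, adjusted p = 0.00551) and X by 0.16 (SE 0.05, adjusted p = 0.0498). Chromosomes 14, 22, 11 and 12 fell, with log2 changes of -0.09, -0.07, -0.06 and -0.04 (limma adjusted p of 0.0319, 0.0436, 0.0370 and 0.0498). Shares are relative, so rises on some chromosomes lower the shares of others. No model by chromosome was rescaled or left out the segments that shifted as a block, which lie on chromosomes 4, 11, 13 and 18. The segment of chromosome 11, from 0 to 15 Mb, had a lower pileup of shared peaks in CRAMP1-KO. Not all of these calls were firm. Chromosome 6 lost its call in lists of equal length (log2 change 0.06, limma adjusted p = 0.138), and chromosome X lost its call in those lists (adjusted p = 0.145), by covered bases, among peaks with −log10 q of at least 10, without WT replicate 3 and without any 1 CRAMP1-KO library. The log2 change of X shrank to 0.09 in lists of equal length, 0.11 by covered bases and 0.05 at the limit of 10. Without 1 of the libraries just named it stayed at 0.15 to 0.19. Chromosome 12 lost its call by covered bases (log2 change -0.03, limma adjusted p = 0.0714) and in lists of equal length (-0.03, adjusted p = 0.0619). Chromosome 22 lost its call in lists of equal length with a change of -0.06, close to the -0.07 of the deposited lists (limma adjusted p = 0.281). With any 1 CRAMP1-KO library left out, limma called 0 chromosomes lower, with 8, 6 and 8 chromosomes of either direction at an unadjusted p under 0.05, while it called 11 lower without WT replicate 1 and 1 without WT replicate 2 or 3. Log2 changes without CRAMP1-KO replicate 1, 2 or 3 were -0.09, -0.10 and -0.09 for chromosome 14. They were -0.07, -0.06 and -0.07 for chromosome 22 and -0.06 each time for 11, close to those of all libraries.

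**Figure D3:**
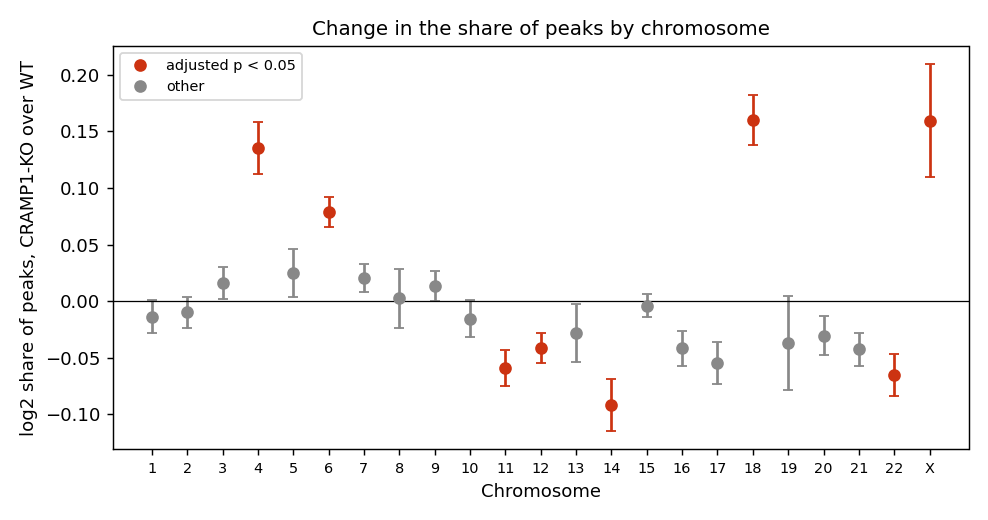
Log2 change of each chromosome's share of peaks, CRAMP1-KO over WT (y axis), for chromosomes 1 to 22 and X (x axis), with bars of 1 SE from limma and calls at an adjusted p under 0.05 in red. Chromosomes 18, 4, 6 and X are called higher, and 11, 12, 14 and 22 lower.

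At finer scale, bins with a higher share of peaks in CRAMP1-KO, called gains below, were spread over 21 chromosomes and held few peaks. Of 2828 bins of 1 Mb, limma called 508 higher and 189 lower, 72.9% of calls being higher. The higher bins held a median of 19.5 peaks per WT library and the lower bins 99.3, against 46.3 over all tested bins. These WT counts also entered the calls, so the medians are not separate support. Scaled to the median log ratio over bins, in place of the library's total, the split was 359 higher and 384 lower, or 48.3% higher. All 359 and 189 of the 384 were called in the same direction under the first scaling, and 0 bins were called in opposite directions. In lists of equal length limma called 317 higher and 105 lower, and without CRAMP1-KO replicate 1, 2 or 3 it called 313, 248 and 259 higher and 99, 81 and 93 lower. Without WT replicate 2 the lower calls numbered 120.

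The largest gain lay at 69 to 70 Mb of chromosome 18, which rose by 1.93 on the log2 scale (SE 0.18, limma adjusted p = 1.18e-05), from 10.7 ± 6.35 to 34.7 ± 4.51 peaks per library (SD, n = 3). It belonged to a run of higher bins from 61 to 72 Mb, and a run from 23 to 45 Mb of the same chromosome was led by the bin at 27 Mb, up by 1.17 (limma adjusted p = 0.000422). From 20 Mb on, 47 of the 58 tested bins of chromosome 18 were higher and 0 lower, and below 20 Mb 0 of 18 were higher and 6 lower. Outside chromosome 18 the largest gains were at 74 Mb of chromosome 3, 127 Mb of chromosome 4 and 67 Mb of chromosome 6, with log2 changes of 1.39, 1.33 and 1.31 (limma adjusted p of 0.000136, 0.000993 and 0.00203). These bins held few peaks, with WT means of 5, 4 and 6.33. The summit pileup of shared peaks from 20 to 75 Mb of chromosome 18 was also higher in CRAMP1-KO, by 0.38 on the log2 scale, in a segment picked for such a shift.

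**Figure D4:**
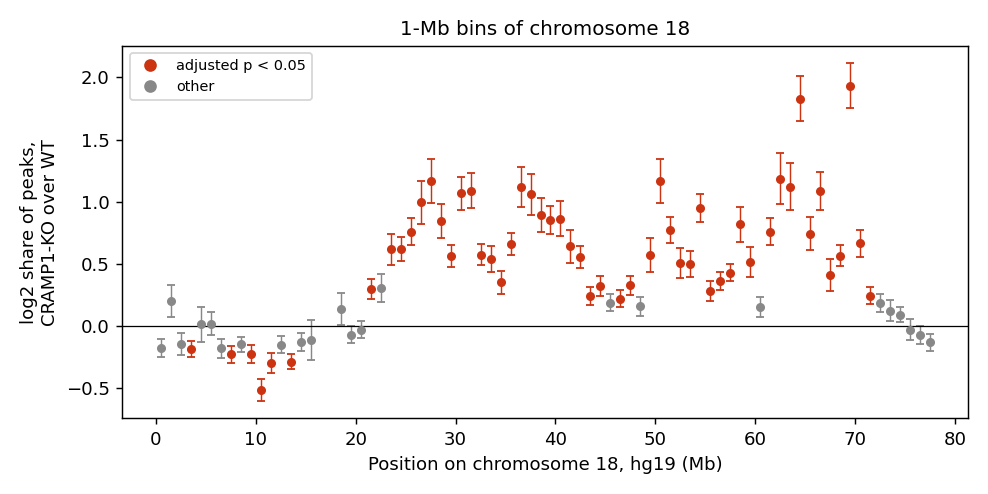
Log2 change of the share of peaks in each tested 1-Mb bin of chromosome 18, CRAMP1-KO over WT (y axis), by position in hg19 (x axis), with bars of 1 SE from limma and calls at an adjusted p under 0.05 in red. The higher calls, 47 bins, lie from 20 Mb on, and the 6 lower calls lie below it.

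On the log2 scale the largest losses were smaller than the largest gains. In peaks per library this did not hold, as the bin at 1 Mb of chromosome 11 fell from 131 ± 29.5 to 76.7 ± 12.7 (SD, n = 3). The bin at 5 Mb of chromosome 1 fell by 0.76 on the log2 scale (SE 0.11, limma adjusted p = 0.000295), from 47.3 ± 7.23 to 25 ± 4.58 peaks per library (SD, n = 3). Bins at 19 and 101 Mb of chromosome 13, 178 Mb of chromosome 5 and 1 Mb of chromosome 11 had log2 changes of -0.63, -0.62, -0.61 and -0.61 (limma adjusted p of 0.00129, 0.00399, 0.000248 and 6.04e-05). The call at 19 Mb of chromosome 13 was lost among peaks with −log10 q of at least 10 (limma adjusted p = 0.619). The bins at 101 Mb of chromosome 13 and 1 Mb of chromosome 11 lie in segments where the pileup of shared peaks was lower as a block in CRAMP1-KO. In the 5-Mb bin that starts at 5 Mb of chromosome 1, pileup and local background of shared peaks were lower too, with log2 shifts of -0.25 each.

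Of 25 windows at gene clusters and key genes, 23 held a peak in any library and 5 had peak shares without overlap between genotypes, where chance gives 10%, or 2.3 of the 23. By covered bases there were 6, of which 5 were lower in CRAMP1-KO. None passed the adjustment over windows (exact permutation, lowest adjusted p of 0.5 by peaks and 0.417 by covered bases). The HOXC cluster of developmental transcription factors held 2.46 ± 0.1 peaks per 10000 in WT and 2.10 ± 0.231 in CRAMP1-KO (SD, n = 3), and its covered bases did not separate the genotypes. The 11p15 region of beta-globin and olfactory receptor genes held 9.14 ± 0.122 and 8.28 ± 0.127, and the epidermal differentiation complex, a cluster of genes of the skin barrier, 10.2 ± 0.0832 and 9.69 ± 0.162 (SD, n = 3). The 11p15 region lies inside the segment from 0 to 15 Mb of chromosome 11 where the pileup of shared peaks was lower as a block. Among peaks with −log10 q of at least 5, the difference at the epidermal differentiation complex shrank from -0.493 to -0.0737 per 10000 (exact permutation p = 0.8; p = 0.7 at a limit of 10), and HOXC (exact permutation p = 0.5) and interferon-alpha (exact permutation p = 0.4) overlapped at the limit of 5 and were apart again at 10 (exact permutation p = 0.1 each). The interferon-alpha cluster at 9p21, genes of antiviral signalling, went the other way, with 1.09 ± 0.127 in WT and 1.27 ± 0.0542 in CRAMP1-KO (SD, n = 3). H1-4 was the fifth, with the split peaks given above. The major histone gene cluster at 6p22 held 14.5 ± 1.02 and 14 ± 0.712 peaks per 10000, a difference within the spread (SD, n = 3; exact permutation p = 0.5). The number of such windows was 9 without WT replicate 1 or CRAMP1-KO replicate 1 and 8 without WT replicate 3. It was 7 without WT replicate 2 and 5 without CRAMP1-KO replicate 2 or 3. Chance with 3 libraries against 2 gives 20%, or 4.6 of the 23.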

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

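The tests in this part were chosen after the results were seen, except that for the correlation within chromosomes and that with the strictest peaks the bounds were set before those values were computed, and that the ratio of gene-poor to gene-rich chromosomes and the median width in lists of equal length and at stricter q limits were planned. The 10 splits of 3 and 3 libraries are too few for a share under 0.05.

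Pileup at the summits of shared peaks, which no comparison of the report tests, was higher in every CRAMP1-KO library than in every WT library by 0.38 on the log2 scale from 20 to 75 Mb of chromosome 18 (1250 regions) and by 0.40 from 60 to 75 Mb of chromosome 4 (216 regions). It was lower, with log2 shifts of -0.44, from 75 to 115 Mb of chromosome 13 (646 regions) and -0.44, from 0 to 15 Mb of chromosome 11 (636 regions). These segments were picked from the same values, as runs of at least 3 adjacent 5-Mb bins with at least 20 shared regions each. Every bin of a run had to shift by at least 0.25 in the same direction, without overlap between genotypes. The size and separation of these shifts thus follow from the rule and are no test. A copy-number difference between the cell populations would move strong and weak peaks alike, and the strongest 25%, relative to peaks of like strength elsewhere, moved by 0.392 on chromosome 18, -0.398 on 13 and -0.30 on 11, next to 0.33, -0.33 and -0.36 for the weakest 25%, which is consistent with copy number there. The local background moved too, by 0.43 on 18, -0.42 on 13 and -0.44 on 11. It was solved at the same summits as the pileup. In called bins outside the segments it moved with the pileup as well, by 0.26 beside 0.25 in higher and -0.13 beside -0.13 in lower bins. The background is therefore no separate evidence for copy number. On chromosome 4 it rose by 0.23 (SD 0.0723), which copy number and accessibility could both give. The strongest 25% moved there by only 0.047 (SD 0.039, 42 regions) and the weakest by 0.27, so copy number cannot be told apart from accessibility there. Whether such differences came with the knockout, with a clone or with culture was not tested, and regional accessibility stays open beside them.

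The larger share of peaks on the gene-poor chromosomes as a class and in peak-poor bins was set against technical explanations. If depth or list length were the cause, libraries of like depth would be alike, but the lowest difference in the gene-poor over gene-rich ratio between such libraries was 0.0822, above the within-genotype SDs of 0.0179 and 0.0114. In lists of equal length the difference was 0.0774, without overlap, with larger SDs of 0.0369 in WT and 0.0275 in CRAMP1-KO. Without the 4 segments the gene-poor excess was 0.0532 in place of 0.0823, or 10.3% in place of 12.4% of the WT ratio, still without overlap. With them left out the change in bins fell with peak number within 22 of 23 chromosomes, chromosome 19 being the exception. Shorter stretches outside the segments also moved in both pileup and background. Among 5-Mb bins, the log2 shifts were -0.25 and -0.25 at 5 Mb of chromosome 1 and -0.30 and -0.28 at 65 Mb of chromosome 11. They were 0.35 and 0.30 at 45 Mb of chromosome 14. Leaving out the segments thus does not remove every regional copy-number difference that may exist. Weak calls near the deposited threshold were not its only source. Peaks with −log10 q of at least 10 alone gave a median log2 change of 0.33 in the 10% of bins with fewest peaks, against at most 0.05 between libraries of one genotype. A stricter limit only moves the threshold, so this cannot exclude weaker sites that cross whichever limit is used. Outside the segments the pileup of the strongest 25% of shared peaks was lower in CRAMP1-KO by -0.13 on the log2 scale (exact permutation p = 0.1, no overlap) and that of the weakest did not separate (-0.00146, exact permutation p = 1). In higher bins the strongest moved by 0.003 (0.136 relative to peaks of like strength) and the weakest by 0.28, in bins picked for their change. A lower contrast between strong and weak sites therefore stays open. So do copy number outside the segments, a difference between clones or cultures, and an effect of losing CRAMP1.

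Wider peaks in CRAMP1-KO may come in part from list length, because the difference in median width was 37.8 bp, with overlap, in lists of equal length. Among peaks with −log10 q of at least 10, which numbered 96166 ± 11956 in WT and 93746 ± 10978 in CRAMP1-KO (SD, n = 3), the widths were 529 ± 15.6 and 590 ± 19.9 bp without overlap (exact permutation p = 0.1), so these values do not settle it. On 83398 regions with 1 peak in each library the widths were 538 ± 44.6 and 587 ± 30.7 bp (exact permutation p = 0.3). Fragment length cannot be told apart from genotype here: the ratio of median to lowest width stayed apart by 0.113, with a within-genotype SD of 0.0691, and the lowest width is only a stand-in for fragment length.

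The split counts bear on the report's models as follows. The genotype split gave 697 bins past the threshold in limma and the highest other split 0, with 1 of 10 splits giving as many, and up to 160 bins at an unadjusted p under 0.05 in the others. For chromosomes it gave 8 against 1 (1 of 10 splits), for genotype-specific regions 4725 against 3292 in deposited lists and 4430 against 1509 in lists of equal length (1 of 10 splits each). These region counts sum both directions. In the deposited lists WT replicates 1 and 2 with CRAMP1-KO replicate 3, the deepest libraries, had 3216 regions of their own. That is above the 2823 WT-only regions, so a split by depth can give as many in a single direction. In lists of equal length the same split gave 940, under the 1859 WT-only regions.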

How the results depend on the processing

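Leaving out the segments or chromosome 18 was chosen after seeing the data. The gene-poor over gene-rich ratio was higher in CRAMP1-KO under every alternative run, by 0.0532 to 0.0925, and the mean similarity within genotypes stayed above that between genotypes. With −log10 q of at least 10 there were 1230 CRAMP1-KO-only and 1188 WT-only regions, and limma called 8 chromosomes lower (7 at a limit of 5). Regions in at least 2 of 3 libraries and in 0 of the other numbered 6593 and 12685, a looser rule by construction. Lists of equal length gave 1859 WT-only regions and 317 higher and 105 lower bins. Scaling to the median log ratio gave 384 lower bins, and 5-Mb bins, being fewer, 182 higher and 65 lower. Without the segments there were 449 higher and 164 lower bins. Other causes were not tested.

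Leaving out each library in turn gave -31596 to 1499 for the difference in peaks per library, -6.36 to 7.65 Mb for that in covered length (-3.64 without CRAMP1-KO replicate 3), 2164 to 4523 CRAMP1-KO-only and 3525 to 8696 WT-only regions, 5 to 9 windows without overlap, 248 to 620 higher and 81 to 255 lower bins and 0 to 11 lower chromosomes. Fewer libraries loosen the region rule by construction. Of the named bins and chromosomes, 143 and 58 values kept direction and call and 1 and 30 kept direction only. Chromosomes 18 and 4 held under all alternatives run for chromosomes. None of these left out the segments, so the calls of chromosomes 18 and 4 may rest on the segments they hold. Chromosome X had adjusted p of 0.0543 to 0.147 in the 7 alternatives that lost its call.

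Replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.025, -0.07 and -0.025. With a replicate block limma called 463 higher and 169 lower bins, and 4 higher and 3 lower chromosomes, chromosome 12 not being called (adjusted p = 0.134). Overlap of at least 0.5 of the shorter and the summit rule change nothing, because every peak lies wholly inside its region. Annotation classes and promoter gene lists, with their alternatives, were not run. Depth limits absence: a missing peak is a site not called at that library's depth.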

Other observations

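The 3 tests in this part (bins, gene density and split regions) were chosen after the results were seen. The change in the share of peaks followed how many peaks a 1-Mb bin held. With bins ordered by WT replicate 1 and the change taken against WT replicates 2 and 3, the 10% of bins with fewest peaks (4 to 15) had a median log2 change of 0.43 and the 10% with most (146 to 262) -0.12, with each step of 10% below the one before. In the poorest 10%, 90.8% of bins were higher in CRAMP1-KO, and in the richest 10%, 7.42%. Between WT replicates 2 and 3 the medians of these steps ran from -0.02 to 0.01. Across bins, which are not independent replicates, Spearman's rho with the segments left out was -0.72, against at most 0.162 in size between libraries of one genotype. A gain of called sites in peak-poor chromatin of the CRAMP1-KO cells is consistent with this, as a hypothesis from these data alone, and a lower contrast between strong and weak sites stays open beside it.

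Whether chromosomes follow their density of protein-coding genes, counted in the GRCh38.p14 gene table, was less clear. Over 23 chromosomes Spearman's rho was -0.552 (permutation p = 0.0069, adjusted over 4 relations 0.028) and Pearson's r was -0.374 (permutation p = 0.084, adjusted 0.084). Without chromosome 18 rho was -0.503 (permutation p = 0.018, adjusted 0.036). Without the 4 chromosomes that hold segments rho was -0.44 (permutation p = 0.06, adjusted 0.079), which does not pass the threshold. Chromosomes are not independent replicates of a cell population.

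Shared regions split into several peaks at different rates. More than 1 peak lay in 5.53%, 3.35% and 5.03% of the regions shared by all libraries in WT and in 2.15%, 2.96% and 2.11% in CRAMP1-KO (exact permutation p = 0.1, no overlap, n = 3). The lowest peak width, a stand-in for fragment length, was 135, 163 and 147 bp in WT and 163, 158 and 168 bp in CRAMP1-KO, and the relation between width and rate was not tested.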
